A study of Homo sapiens with 32 samples.

How the data were processed

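RNA decay was followed by pulse labelling with 4-thiouridine (4sU), a uridine analogue built into newly made RNA, in MDA-MB-231, an established human breast cancer cell line, and MDA-LM2, its derivative selected for lung metastasis. The labels list 32 libraries of precipitated labelled RNA, 4 for each line at 0, 2, 4 and 7 h after a pulse of 2 h. Values per library were not used here, because the tables hold 1 decay rate per transcript for each of 4 replicate series per line, each series spanning the 4 time points. The sources do not say whether the series came from separate cultures, so p-values measure only the spread between these series.

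The deposited decay rates are positive where abundance fell with time, per the file headers and the labels. Their log base, the scaling between time points and the treatment of zeros are not given in the sources used here, so no rate was turned into a half-life. TopHat, Cufflinks and the build hg18 are named without versions or roles in the submitters' processing notes. The authors also deposited a differential score per transcript, headed as a t-score. It equalled, within 0.001 for all 12966 transcripts in both tables, the sign of the MDA-MB-231 minus MDA-LM2 mean rate times 1 minus a two-sided p of an unequal-variance comparison of the rates. A positive score thus marks slower decay in MDA-LM2. Read depth is unknown, and no interval that needs it is given.

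Symbols came from a RefSeq gene table of a later assembly (12644 accessions) and from GENCODE (114); 208 accessions had no symbol. Because the builds differ, no coordinate is given. A gene's value was the median over its transcripts, which gave 10827 genes, 9136 of them with a single transcript. No column was left unmapped to a line.

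The plan fixed before the data were examined foresaw either abundances per library or a single rate per line. For tables of rates it foresaw no test beyond counting the deposited statistic at a Benjamini-Hochberg adjusted p of 0.05, and that count is the main result per transcript. The tables turned out to hold 4 rates per line. A limma fit (version 3.58.1 in R 4.3.3, variance trend, no block, two-sided, Benjamini-Hochberg) of the 4 against 4 rates was therefore added after the tables had been seen, on transcripts and on genes, and every adjusted p of a gene comes from it. The camera test of gene lists (preset correlation 0.01 and estimated correlation) was added in the same way. In all, 27 limma settings were run on genes: the fit itself, 7 alternatives listed in advance (most of them for a fit on abundances) and 19 added later, among them every one that restricts the range of rates or models correlation between series. The closing section gives the counts they produced.

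The fit was tested on simulated data with 100 features changed by 0.3 and 100 by 0.1. On genes with independent noise it recovered 56% of the differences of 0.3 and 8% of those of 0.1, with 7.25% false calls. With noise shared by series as estimated from the data, false calls rose to 27.2%. A fit with a correlation between these series gave 14.3%. A fit on means of such series recovered 0% of either size, so its low counts say nothing about differences of these sizes. Changed features were drawn from those with all rates within 1 of 0, and larger differences were not simulated. limma's variance trend also gave large errors at extreme mean rates: CELF2 and SLA2 differed by about 8 between the lines, in both disjoint sets of series, yet had an adjusted p of 0.996, while the unequal-variance statistic called both.

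Within each line, the median rate of 24 gene lists fixed before the data were examined was placed among 10000 random lists of the same size. Differences between lines were placed among 10000 random lists matched on mean rate in 20 bins. Draws were with replacement, and lists with fewer than 3 measured members (endothelial and fibroblast markers, immune cell markers) were not tested. Medians relative to all genes were compared by a two-sided exact permutation test of 4 against 4 series, whose smallest p is 0.0286. Every exact permutation test takes the series as exchangeable, although series with the same second number share noise, and only 3 splits keep these together. The shift between lines has a bootstrap 95% interval over genes (1000 draws), which covers the choice of genes only. Genes named in the text followed a rule fixed in advance: 12 decreases and 12 increases past adjusted p 0.05, ranked by the deposited score (thus by p, not by size) with ties by alphabet and with symbols starting LOC, MIR or SNOR and readthrough genes passed over; the 5 fastest and 5 slowest; from each list the 3 largest differences and the fastest member; and TARBP2, APP and ZNF395. Not every gene the rule selects is reported here. Python 3 tools were numpy, scipy, pandas and matplotlib.

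Rates beyond 1 either side of 0 formed separate clusters. After this was seen, genes with all 8 rates within 1 of 0 (7223 of 10827) were analysed separately as genes in range, and the naming rule was repeated on them. Alternatives that need abundances per library (pseudocount, abundance filter, omission of 7 h, size factors) or a fit quality column could not be run.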

Results

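Decay of newly made RNA was compared between MDA-MB-231 breast cancer cells and MDA-LM2, the derivative selected for lung metastasis. The study asked which transcripts differ in stability between them. Both rate tables held 12966 transcripts of 10827 genes, with 4 replicate series per line. Rates are in the deposited unit, and errors are SDs over the 4 series of a line. The median rate over genes was 0.165 ± 0.0106 in MDA-LM2 and 0.189 ± 0.0152 in MDA-MB-231 (n = 4 series each, two-sided exact permutation p = 0.0571).

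Some gene groups decayed slowly in both lines and others fast in both. Cytosolic ribosomal protein transcripts were the slowest of the lists tested, with a list median of -0.0281 ± 0.00885 in MDA-LM2 and 0.0539 ± 0.0132 in MDA-MB-231 (78 genes). Transcripts of nuclear-encoded oxidative phosphorylation subunits (73 genes, 0.0191 ± 0.0187 and 0.0964 ± 0.0199) and of the proteasome, the main protein-degrading complex (31 genes, 0.028 ± 0.00527 and 0.0925 ± 0.011), were also slow. Each of these 3 lists lay at percentile 0 of random lists in both lines. Immediate early genes, which growth signals switch on briefly, decayed fastest (27 genes, 0.538 ± 0.04 and 0.448 ± 0.05, percentile 100 in both lines). Histone genes (37 genes, 0.394 ± 0.0258 and 0.305 ± 0.0491) lay at percentile 100 in MDA-LM2 and in MDA-MB-231 just inside the middle 95% of random lists. Zinc finger genes (343 genes, 0.283 ± 0.0134 and 0.292 ± 0.0368) lay at percentile 100 in both lines, and inflammatory cytokines and NF-kB targets (16 genes) at 99.6 in both. Other lists had unlike percentiles within the lines, with interferon-stimulated genes at 99.2 in MDA-MB-231 and 33.6 in MDA-LM2 and glycolysis at 17.1 and 0.08. Their differences between the lines lay inside the middle 95% of matched lists (84.7 and 16.8), so no difference between the lines is read from these percentiles. Outside the middle 95% of random lists lay 8 slow lists in MDA-LM2 and 6 in MDA-MB-231, and 4 fast lists in each line.

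**Figure D1:**
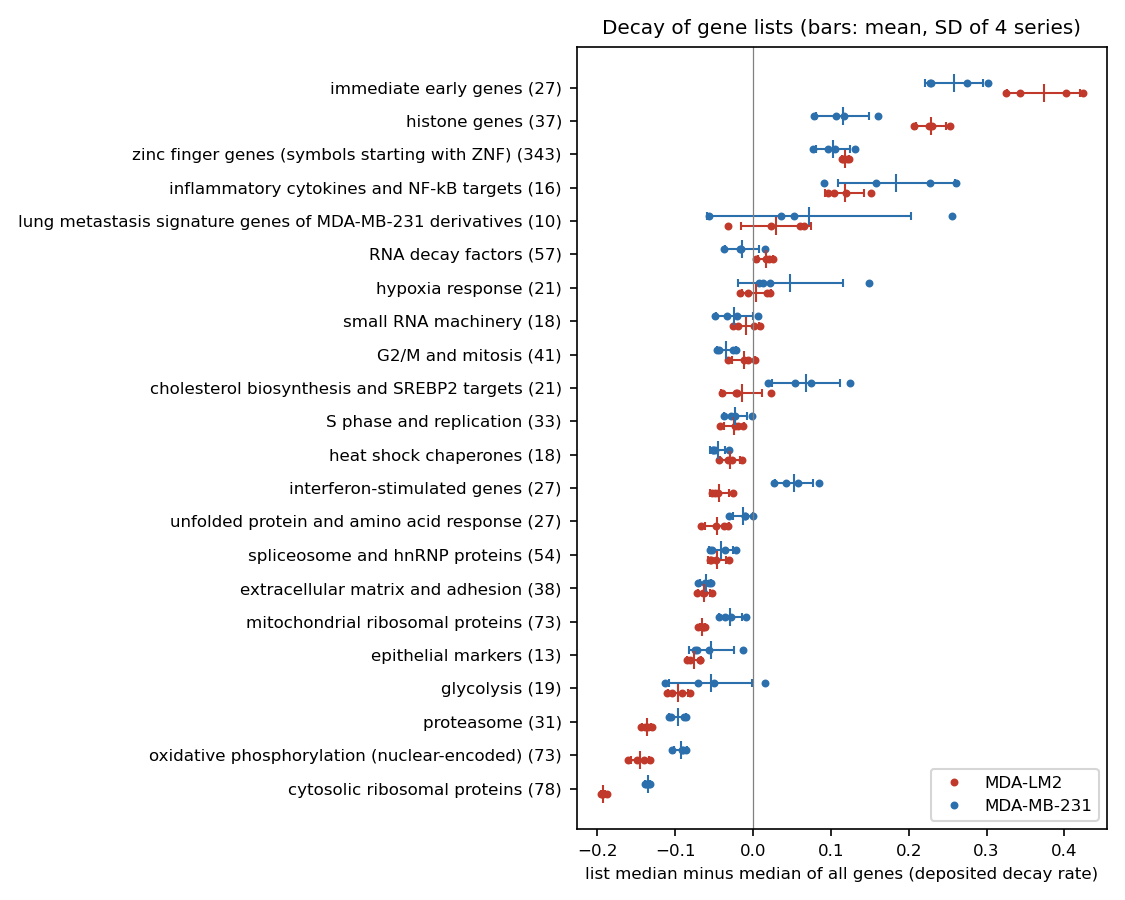
Median decay rate of each gene list minus the median of all genes, in the deposited rate unit; points are series, bars the mean and SD of 4 series per line, and numbers in parentheses the measured genes. Cytosolic ribosomal proteins lie lowest, at -0.193 ± 0.00311 in MDA-LM2 and -0.136 ± 0.00285 in MDA-MB-231, and immediate early genes highest.

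The genes at the ends of the range had rates far outside the bulk. KTI12 was the fastest, at 9.32 ± 0.0698 in MDA-LM2 and 9.44 ± 0.0758 in MDA-MB-231. ZNF790-AS1, SMIM27, SOCS2 and DNAJB5 followed, each with 1 series far from the other 3 in 1 line. FBXO9, CELF2, SLA2, OSBPL6 and TMEM222 had the lowest mean rates. CELF2, an RNA-binding splicing regulator, stood at 0.169 ± 0.108 in MDA-LM2 and -8.24 ± 0.0719 in MDA-MB-231. Rates beyond 1 either side of 0 made up 3.96% ± 0.793 of gene values in MDA-LM2 and 17.5% ± 0.882 in MDA-MB-231 (n = 4 series each, exact permutation p = 0.0286, the smallest possible). Among genes in range, the fast ones included BHLHE40 (0.639 ± 0.0437 and 0.716 ± 0.236) and DUSP1, a phosphatase of the MAP kinases (0.63 ± 0.161 and 0.594 ± 0.167), both named after their values were seen.

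**Figure D2:**
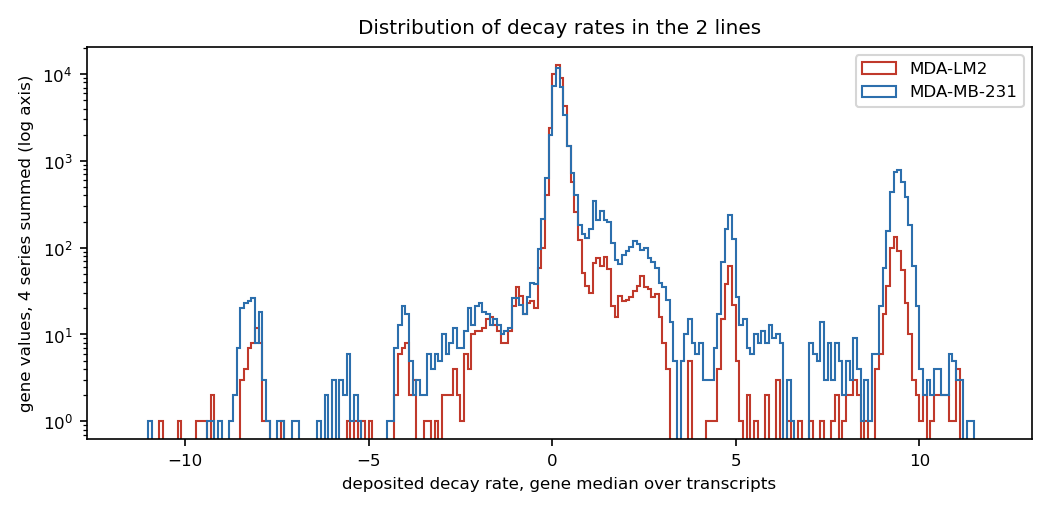
Number of gene values (log axis) against deposited decay rate, the 4 series of each line summed. Besides the main peak near 0 there are separate clusters, and rates above 1 make up 3.37% of values in MDA-LM2 and 16.3% in MDA-MB-231.

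More transcripts decayed slowly in MDA-LM2 than fast, relative to MDA-MB-231. By the score in the authors' deposited table, 582 transcripts passed a Benjamini-Hochberg adjusted p of 0.05 as slower in MDA-LM2 and 139 as faster, of 12966. The limma fit added after the tables were seen called 783 slower and 246 faster. On genes it called 726 slower and 217 faster of 10827. These counts and those by the score treat the 4 series of a line as independent, although series with the same second number share noise. With each series centred on its median, the gene split was 559 slower and 434 faster. With a correlation between series that share the second number of their label, 345 slower and 36 faster were called, of which 99 and 34 were in range (443 and 214 without the correlation). Genes in range fitted alone with that correlation gave 1 and 0 (1311 at an unadjusted p of 0.05; 529 and 265 without the correlation). The call of most single genes in range thus depended on treating the 4 series as independent.

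The 12 decreases that ranked first tied at the limit of the score, which grows with 1 minus p and not with the size of a difference, and were AGR2, ALOX12-AS1, ANKRD37, BRF2, C3orf49, CCDC146, CCDC85B, CLDN24, CLUL1, DENND2D, DEXI and EFL1P1, the first by alphabet. All had MDA-MB-231 rates in the cluster near 9.5. A zero at 7 h replaced by a tiny value stays open as the source of that cluster. AGR2, a disulfide isomerase of secretory cells, had -0.156 ± 0.119 in MDA-LM2 and 9.31 ± 0.111 in MDA-MB-231 (limma adjusted p = 7.79e-05). Of the 726 genes called slower, 283 had a rate beyond 1 in some series and 143 had all 4 MDA-MB-231 rates above 8. Other genes of this kind were NFKBIA, the inhibitor of NF-kB (0.489 ± 0.216 and 9.7 ± 0.065), DDIT4 (0.261 ± 0.0438 and 9.45 ± 0.0853), STAU2 and MRPL36. GAPDH (1.49 ± 0.0575 in MDA-MB-231), AURKB and CAV2 are medians over 2 transcripts.

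Among genes past the limma adjusted p of 0.05, the 12 increases that ranked first by the score began with PDCD1LG2, an immune checkpoint ligand (9.31 ± 0.051 in MDA-LM2 and 0.312 ± 0.0651 in MDA-MB-231), and MARS2. The other 10 were in range: DDX42, CCN1, BCORL1, SLC10A3, PANK4, PRRC2C, ZNF827, FOSL1, KIF14 and KAT2B. The limma condition left out CELF2 and SLA2, both out of range, although the unequal-variance statistic called both as faster in MDA-LM2. The share of top increases in range thus depends on that condition. FOSL1, a subunit of the AP-1 transcription factor, had 0.557 ± 0.0354 and 0.307 ± 0.0407 (limma adjusted p = 0.00622; 0.0314 with correlated series). CCN1, a secreted matrix protein, had 0.806 ± 0.0348 and 0.512 ± 0.0375 (0.0114; 0.0556 with correlated series). KAT2B, a histone acetyltransferase, had 0.144 ± 0.0137 and 0.0257 ± 0.00459 (0.00152; 0.0121 with correlated series). When genes in range were fitted alone with correlated series, all 3 missed the threshold, with limma adjusted p of 0.106 for FOSL1, 0.0951 for CCN1 and 0.0865 for KAT2B.

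Among genes in range, chosen after their values were seen, the decreases that ranked first by the score were HSDL2, EIF2S3, POLDIP2, RACK1, PRDX4, GLIPR1, SLC4A7, PSMA2, KDELR2, NAA50, ATP6V1C2 and NUP43. HSDL2 had 0.00805 ± 0.00567 in MDA-LM2 and 0.165 ± 0.00778 in MDA-MB-231 (limma adjusted p = 0.000171; 0.0011 with correlated series). PRDX4, a peroxiredoxin, had -0.0881 ± 0.0112 and 0.0822 ± 0.018 (0.00023; 0.0028). PSMA2, a proteasome subunit, had -0.0359 ± 0.0148 and 0.0888 ± 0.00877 (0.00102; 0.00508). RACK1, a ribosome-bound scaffold, had -0.0278 ± 0.00399 and 0.0288 ± 0.00501 (0.0147; 0.0735). The RACK1 difference of -0.0566 was small beside the median size of 0.129 among called genes in range. When genes in range were fitted alone, RACK1 missed the threshold (limma adjusted p = 0.0694). With correlated series in that fit all 4 missed it, at 0.0576 for HSDL2, 0.0855 for PRDX4, 0.0865 for PSMA2 and 0.264 for RACK1.

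**Figure D3:**
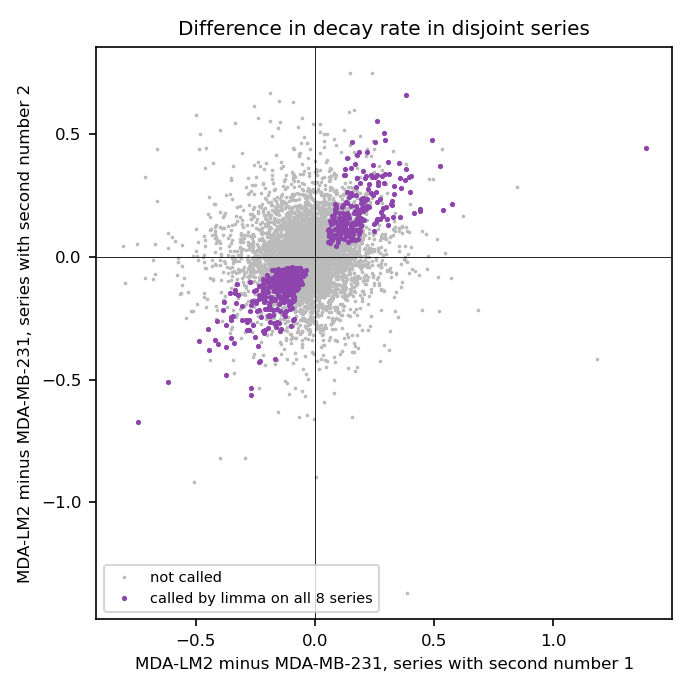
Difference in decay rate (MDA-LM2 minus MDA-MB-231, deposited unit) for 7223 genes in range, from the series with second number 1 (horizontal) and 2 (vertical); purple points passed limma on all 8 series, which selects genes with the same sign in both. Across all genes shown, Spearman rho is 0.221 and 59.6% have the same sign.

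Of all 10827 genes, 7250 (67%) had a lower mean rate in MDA-LM2, and member counts of lists are to be read against that share. Cytosolic ribosomal proteins had lower rates in MDA-LM2 in 72 of 78 members. Adjusted over all genes, limma called 34 slower and 0 faster, against 17 slower with correlated series. Adjusted over the list alone, without that correlation, 50 were slower. Relative to all genes, their median was -0.193 ± 0.00311 in MDA-LM2 and -0.136 ± 0.00285 in MDA-MB-231 (percentile 0 of matched lists). The camera adjusted p was 1.37e-10, and adjusted p = 0.271 with an estimated correlation. The members of largest difference, RPL31, RPL41 and RPL34, did not pass, with MDA-MB-231 SDs of 4.74, 0.765 and 0.883. The proteasome list had 29 of 31 members lower and 8 called slower, against 2 with correlated series. Adjusted over the list alone, without that correlation, 19 were slower. It lay at percentile 0.75, with a camera adjusted p of 6.99e-05, and adjusted p = 0.271 with an estimated correlation. PSMD1 had -0.0621 ± 0.111 and 1.09 ± 0.586 (limma adjusted p = 0.0494, and 0.222 with correlated series). Oxidative phosphorylation had 59 of 73 members lower and 12 called slower, against 3 with correlated series. Adjusted over the list alone, without that correlation, 19 were slower. It lay at percentile 0, with a camera adjusted p of 0.0497, and adjusted p = 0.38 with an estimated correlation. NDUFC1 had 1.08 ± 1.54 and 7.7 ± 3.48 and did not pass. For genes in range, rates simulated with a common factor between the lines and noise alone put a median of 6 of 6 lists beyond the percentile limits (these 3 and histone, immediate early and zinc finger genes). The percentiles thus do not tell a difference of 1 list from such a factor. Against random lists not matched on mean rate, cytosolic ribosomal proteins lay at 5.41, oxidative phosphorylation at 3.49 and the proteasome at 22.5, all inside the limits.

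Histone genes had higher rates in MDA-LM2 in 25 of 37 members, of which 3 were called faster, also when adjusted over the list alone, and 0 with correlated series (limma). Relative medians were 0.229 ± 0.0191 and 0.115 ± 0.0343, the camera adjusted p was 6.99e-05, and adjusted p = 0.271 with an estimated correlation. H2BC7 had 8.78 ± 0.368 and -1.66 ± 8.72. Immediate early genes had relative medians of 0.374 ± 0.0468 and 0.258 ± 0.037 and lay at percentile 99.9 of matched lists. Their median gene difference was negative (-0.107) while the list median was higher in MDA-LM2, and in range the median difference was 0.165. Members outside that range included ID3 (5.11 ± 5.15 and 9.63 ± 0.0493) and IER2. The camera adjusted p was 0.101, and 4 members were called faster and 1 slower (1 and 0 with correlated series). Zinc finger genes (7 called faster and 24 slower of 343, 1 and 19 with correlated series) lay at percentile 100 with a negative median difference of -0.0521, which was 0.0227 in range. Their 7 and 24 calls were near the share over all genes (217 faster and 726 slower of 10827). Against lists not matched, histone genes stayed at 100, while immediate early genes lay at 8.63 and zinc finger genes at 57.4. In the exact permutation test of relative medians, several lists reached the smallest possible p of 0.0286. These were cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, proteasome, histone, immediate early, interferon-stimulated and unfolded protein genes. Benjamini-Hochberg adjustment over 22 lists brought this floor to 0.0786. An adjusted p below 0.05 would have needed more lists at the floor, so missing it does not argue against a difference.

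Other lists lay outside the middle 95% of matched lists without a camera call. Mitochondrial ribosomal proteins lay at 1.94, epithelial markers at 0.12 and inflammatory cytokines and NF-kB targets at 0.02, against 97.7 for RNA decay factors. The median difference of RNA decay factors was nonetheless negative (-0.0109). In range all 4 lists lay inside the limits, and the inflammatory list turned to the other side (percentile 92.8, median difference 0.0519). Against lists not matched, inflammatory genes lay at 0.05 and RNA decay factors at 98.3, with mitochondrial ribosomal proteins (13.6) and epithelial markers (6.75) inside. DNAJB1, a heat shock chaperone, had 0.454 ± 0.0467 and 0.24 ± 0.0434 (limma adjusted p = 0.0131; 0.0597 with correlated series, 0.121 with these in range). The lists of G2/M, S phase, cholesterol biosynthesis, extracellular matrix, glycolysis, heat shock, hypoxia, interferon-stimulated, lung metastasis signature, small RNA, spliceosome and unfolded protein genes lay within the limits. The metastasis signature was derived from related cell lines and is not independent evidence. Endothelial and fibroblast markers and immune cell markers had 2 measured members each.

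Across genes, the median difference (MDA-LM2 minus MDA-MB-231) was -0.0539 (bootstrap 95% interval -0.0565 to -0.0504), and -0.0169 in range. In range, the series medians were 0.151 ± 0.0115 in MDA-LM2 and 0.159 ± 0.0155 in MDA-MB-231 (two-sided exact permutation p = 0.457). The series medians thus did not separate the lines in range. The interquartile ranges did, at 0.159 ± 0.00328 in MDA-LM2 and 0.153 ± 0.0027 in MDA-MB-231 (exact permutation p = 0.0286, the smallest possible). The lines correlated across genes with Spearman rho 0.423 and Pearson r 0.316, and genes are not independent replicates. Single series correlated between the lines at a mean rho of 0.324. Within MDA-MB-231, series sharing no number of their label correlated at 0.295, and those with the same second number at 0.706. In MDA-LM2, series sharing no number correlated at 0.616. The rho of 0.423 thus does not separate a difference between the lines from noise in MDA-MB-231. After centring, 2239 genes had a difference beyond 1 toward slower and 252 toward faster decay in MDA-LM2, and each of them had a rate beyond 1 in some series. The balance was nearer to even by centred log2 ratio, with rates of 0 or below left out: 2943 slower and 1384 faster beyond a doubling, and 3496 and 2722 beyond 1.5-fold. The score in the authors' deposited table correlated with the rate difference at rho -0.78 across transcripts, with the sign fixed by its construction (100% of transcripts), and at -0.746 across genes.

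TARBP2, an RNA-binding protein of the small RNA pathway, and APP and ZNF395 were examined because the study is known for them. TARBP2 had 2.48 ± 4.56 in MDA-LM2 and 4.82 ± 5.42 in MDA-MB-231 (limma adjusted p = 0.648), with differences of 0.0778 and -4.75 in the disjoint sets of series. APP had 0.0776 ± 0.0426 and 0.976 ± 1.32 (adjusted p = 0.36), and its difference also changed sign between these sets (-2 and 0.207). ZNF395 had 0.26 ± 0.0237 and 0.216 ± 0.0411 (adjusted p = 0.306). None passed, and for TARBP2 and APP the spread between series exceeded the difference.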

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

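The 3 tests of the frequent extreme rates and the test of a common scale factor, with its simulation, were chosen only after the results were seen; the others in this part were written down before. Of 186 groups of 4 series, 25 held a series far from the other 3. About 9.3 would be flagged by chance if groups were unselected and series independent. The groups included the named genes, many chosen for extreme rates, large differences or small p, and series share noise. The excess is therefore not read as evidence against chance.

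In MDA-MB-231, 16.5% of transcript rates lay above 1 against 3.42% in MDA-LM2, and single series jumped between a cluster and the bulk. A zero at 1 time point, replaced by a tiny value before a straight-line fit, predicts where clusters should lie. The places were set from the cluster of a zero at 7 h (5.4% of values), which was therefore not tested. The clusters for 4 h and 0 h lay within 0.42 of their places. That for 2 h (0.793% of values) was 1.071 away, just beyond the bound of 1 set for the test. This explanation as stated thus fails for the 2 h cluster, and for the 7 h cluster near 9.5 it stays open. Rates above 1 were 4.84 times as frequent as in MDA-LM2 and rates below -1 2.06 times; the ratio of these factors, 2.356 ± 0.79 (SE over series; 2.05 to 2.93 without single series), lay above the 1.5 set as the bound by less than 2 SE, so an even loss of reads over time points is not decided. Transcripts above 8 in all MDA-MB-231 series (261) also decayed faster in MDA-LM2, by 0.1332 over the median of all, so fast decay in both lines may contribute; lower abundance or depth in MDA-MB-231 stays open.

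The calls between the lines far exceed those of regrouped series: 1 of the 35 splits, the real one, gave 1029 transcripts, 943 genes and 794 genes in range, and the highest others gave 3, 5 and 1. Chance can be excluded only if the 8 series are exchangeable; series with the same second number share noise, only 3 splits keep them together, too few for a share under 0.05, and modelling that noise left 1 call when genes in range were fitted alone and 133 of the 657 in range called by the fit on all genes. Unchanged rates simulated with that noise, at a correlation of 0.482 for all genes and both lines, gave a median of 18 calls (highest 37). Under that setting, false calls from treating series as independent are argued against as the whole source of the 794. A correlation that differs between genes or lines was not simulated. If shared noise were all, differences in the disjoint sets of series would be uncorrelated; their rho was 0.221, between the bounds of 0.1 and 0.3 set in advance, so how much of the calls shared noise made cannot be told apart from a difference between the lines. Any handling that differed between the lines is confounded with the line.

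In range, 3 slow lists (cytosolic ribosomal proteins, oxidative phosphorylation, proteasome) lay beyond the limits toward slower and 3 fast lists (histone, immediate early and zinc finger genes) toward faster decay in MDA-LM2; others did not follow, such as extracellular matrix genes, slow in both lines and at percentile 83.1. A common scale factor of the rates (1.63 from the spread of list medians in range) left all 6 beyond the percentiles, 4 of them with the sign of their median kept, but 20 simulations of such a factor and noise alone kept the sign in a median of 3 (1 to 5). This test therefore cannot exclude the factor, which shrank the median difference of cytosolic ribosomal proteins from -0.0738 to -0.00413. A linear adjustment for GC content and length, which explained 3.96% of the spread, moved these genes only from -0.0654 to -0.0502 (percentile 0.01). Linear effects of GC content and length are thus argued against as the whole cause for cytosolic ribosomal proteins. After it, oxidative phosphorylation lay at percentile 0.1 and the proteasome at 2.27. Other forms of dependence and junction density were not adjusted for. A difference in stability of these groups between the lines stays open as a hypothesis, as does uneven scaling of the time points, which was not tested.

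Single series stood apart as follows, given as values. In MDA-LM2 these were BRF2 0.4481, FBXO9 -9.633, NAA50 0.1237, PANK4 0.3151, RPL34 -1.415, SMIM27 0.5339 and TARBP2 9.323, whose other 3 series lay between 0.193 and 0.218. In MDA-MB-231 they were ALOX12-AS1 9.663, BRF2 9.734, C3orf49 9.72, CAV2 5.963, DNAJB5 0.1099, EFL1P1 9.568, FBXO9 -0.0254, NDUFC1 2.488, PRRC2C 0.0727, PSMD1 0.2084, RPL31 9.677, RPL41 0.04779, SOCS2 0.1762, TMEM222 -8.494 and ZNF790-AS1 2.545. Also in MDA-MB-231, 1 series had 2.013% of genes below -1, 1 had a relative list median of -0.03057 for heat shock chaperones, and 1 had 0.1487 for hypoxia response.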

How the results depend on the processing

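Thresholds, the replicate block and leaving out a replicate number in both lines were listed before the data were examined; settings on range, centring, second numbers, correlation, single series, limma and camera were chosen after seeing the data. Unless a reason is given, the cause was not tested. Depth is unknown.

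The deposited statistic called 29 faster and 339 slower in MDA-LM2 at adjusted p 0.01, 282 faster at 0.1, and limma 246 faster. For limma on transcripts and on genes, faster calls were 38 and 39 at 0.01, and 495 and 451 at 0.1; slower calls were 382 and 346, and 1268 and 1215. With the replicate block, they were 31 and 27 faster, 310 and 250 slower. The numbers do not pair the series: same-numbered series of the lines had deviations correlated between -0.0247 and 0.00266 in range. Leaving out replicates gave 47 to 352 and 38 to 283 faster, 448 to 1082 and 397 to 1007 slower. The highest followed omission of MDA-MB-231 replicate 2. Centring gave 442 and 434 faster, and in range 421 and 382. Correlated series gave 37 and 36 faster, 385 and 345 slower; in range 0 and 0 faster, 0 and 1 slower; in range and centred 0 and 5 faster, 0 and 4 slower, against 1508 and 1311 at an unadjusted p of 0.05 without centring. Means of series gave 0 and 0 faster, 0 and 3 slower (1499 and 1336 unadjusted), with no power in simulation. The unequal-variance test gave 139 and 118 faster. Second number 1 alone gave 514 and 450 faster, 2007 and 1840 slower. Second number 2 alone gave 201 and 197 faster, 1153 and 1001 slower. The fit on all series gave 246 and 217 faster, 783 and 726 slower. Each set of series with the same second number thus gave more calls than all series, except for faster decay from second number 2. Series with the same second number share noise, which the spread within such a fit does not show. Counts that treat all series of a line as independent may therefore be too high.

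The shift was -0.356 as a trimmed mean, -0.0169 in range and -0.0235 from second number 2. The Spearman correlation between the lines was 0.39 per transcript, 0.466 for genes with 1 transcript, 0.497 without rates of 0 or below, 0.587 in range, and 0.351 and 0.323 from second numbers 1 and 2. Genes beyond the size limit toward faster were 398 per transcript, 108 without rates of 0 or below, and 502 beyond 2 robust SDs; by log2 ratio they were 1384 beyond a doubling (2943 slower) and 2722 beyond 1.5-fold (3496 slower). The score's rho was -0.78 per transcript and -0.804 for single-transcript genes.

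Lists slower by percentile numbered 3 without rates of 0 or below, in range and from second number 2, and 1 against unmatched lists; leaving out single series gave 3 to 6. Lists faster numbered 2 against unmatched lists and by the deposited score, and 2 to 4 without single series. With an estimated correlation, camera called 0 lists slower and 0 faster on all genes, 0 and 0 in range, and 1 and 0 on all genes centred; in range centred it called 2 slower (cytosolic ribosomal proteins, adjusted p = 0.0331, and oxidative phosphorylation, 0.039) and 0 faster, and with the preset correlation 3 faster in range and in range centred, and 2 from second number 1. Median differences turned positive for RNA decay factors (0.0152 in range, 0.0200 from second number 2), inflammatory genes (0.0519 in range), zinc finger genes (0.0227 in range, 0.00721 from second number 2, 0.151 scaled) and immediate early genes (0.165 in range, 0.0399 and 0.0766 from second numbers 1 and 2, -0.458 to 0.0584 without single series, positive without MDA-MB-231 replicate 2 or 3, 0.677 scaled). Of 1600 refits of named genes, 1358 kept their side of the threshold, 223 lost it and 19 gained it.

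Not run, for lack of abundances per library or a fit quality column: pseudocount, abundance filter, omission of 7 h, size factors with a count test, and a filter on fit quality. The 1.5-fold limit was run only with rates of 0 or below left out.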

Other observations

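The bounds for the 3' UTR test were written down before its result was seen; the other feature correlations had no prediction. Some genes had rates in 1 line's table alone: 771 in MDA-LM2 and 546 in MDA-MB-231. The examples were chosen after their values were seen. With MDA-LM2 rates alone were ICAM1, an adhesion molecule (0.289 ± 0.144), OAS3 (0.09 ± 0.08) and PARP9 (0.121 ± 0.0746), both interferon-stimulated, and HERPUD1 (2.4 ± 0.0568). With MDA-MB-231 rates alone were SPARC, a matrix protein (0.0812 ± 0.00828), MMP1, a collagenase (4.87 ± 5.31), and IFI6 (9.45 ± 0.0705), JUP (9.3 ± 0.0176) and GADD45A (9.42 ± 0.129). The filter behind a gene's presence is not given in the sources used here, so absence from a table is not read as absence of the RNA.

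Within lines, decay rates of genes in range followed transcript structure. Junction density, counted as all exon junctions of the transcript per kb of coding sequence, correlated negatively with the rate. Spearman rho across genes was -0.413 ± 0.00621 in MDA-LM2 and -0.24 ± 0.0341 in MDA-MB-231 (4 series each, 6496 genes). Transcript length correlated positively, at 0.232 ± 0.00779 and 0.113 ± 0.0162. Each of the 9 features tested differed between the lines with an exact permutation p of 0.0286, the smallest possible, and adjusted p = 0.0286. This test takes the 8 series as exchangeable, but series with the same second number share noise, and only 3 splits keep them together, too few for a share under 0.05.

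It was hypothesised that GC-rich 3' UTRs go with faster decay in MDA-LM2. The Spearman correlation of the difference with 3' UTR GC content was 0.13 and 0.08593 in the disjoint sets of series, above the bound of 0.05 in both. The correlation is weak, and coding GC content behaved alike (0.118 and 0.108), so it is not specific to the 3' UTR. MDA-MB-231 rates were also noisier: series with different second numbers and first numbers correlated at 0.361 in range against 0.774 in MDA-LM2, and noisier rates alone may weaken such correlations in that line. They do not account for the density of the motif ATTTA in 3' UTRs, whose rho was farther from 0 in MDA-MB-231 (0.0465 ± 0.0116) than in MDA-LM2 (-0.00115 ± 0.0119).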
